A study of Mus musculus with 7 samples.

How the data were processed

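RNA was measured in 7 mouse libraries of cochlear epithelium, the lining of the developing hearing organ, taken at embryonic day 16. Per the labels, 4 libraries came from Brg1 knockout embryos and 3 from controls. Per the labels, total RNA was extracted with the RNeasy Micro kit and made into libraries with the NEBNext Ultra RNA kit. Neither the Cre driver, the exons deleted nor the number of embryos per library is given in the sources used here. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these libraries. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the genome build mm10. The role and settings of each tool, and whether reads were counted by strand, are not given in the sources used here.

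The deposited count table holds 54532 genes with count-scale values that are not scaled for depth, and these are not raw counts. In all 21283 genes above 0 in every library, each value lay within 0.001 of a multiple of 1 divided by 12. Among the 17795 of these genes whose fraction could tell libraries apart, 1 fraction was shared by knockout replicates 1, 2 and 3 and control replicates 1 and 2, and its complement by knockout replicate 4 and control replicate 3. Whole counts moved by 1 constant per gene and batch, with negative results set to 0, have this form. No label records such a step, so the batches were read from the values alone, and 5 libraries form the larger batch and 2 the smaller. The deposited values are therefore estimated counts, gene counts that had been moved by a constant per gene and batch before deposit, as read from the values and not from the labels. They were rounded to whole numbers before every count test. The design had assumed raw counts, and its test, edgeR's quasi-likelihood test, was kept. An adjustment of this kind keeps differences of counts within a batch, except at values set to 0, and changes log fold changes. In the deposited FPKM table, FPKM times gene length gave whole multiples of 1 step per library for 100% of the values (tolerance 0.01), and 100% of these whole numbers equalled the rounded counts, so the FPKM values carry the same adjustment. The scale of the FPKM values implied library totals of which the count table held 96.4% to 98.7%. Both tables gave a column for each of the 7 libraries, and control replicate 3 by its title is numbered 4 in its description and in both tables. Neither table holds a control numbered 3. Whether such a library, or any other beyond the 7, took part in the adjustment is not stated. Had the constants come from batch means of these 5 and 2 libraries alone, they would not all be multiples of 1 divided by 12. If batch means were used, this argues that at least 1 library beyond the 7 took part.

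Library totals lay between 16098269 and 18872132 counts. The floor used here, 3 counts, corresponded to between 0.159 and 0.186 CPM and covers counting error only. Between 16771 and 17084 genes per library had 10 or more counts. Libraries of 1 group differed by more than counting noise (chi-square per degree of freedom from 12.6 to 23.9). Within a batch, this argues against the same library having been sequenced again. Across batches the adjustment alone can raise this value, so such pairs could not be checked. Gene names were those of the tables, except that 27 names in the form of a date were replaced by the symbol of their gene ID. Of the gene IDs, 99.8% were in GENCODE M21, and 98.1% of the genes had the same coordinates there, on GRCm38, the assembly that mm10 names. Coordinates are those of the tables.

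Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, robust quasi-likelihood F-test, knockout minus control, no covariate, Benjamini-Hochberg adjusted p below 0.05), over 17341 genes. CPM are TMM-scaled. Standard errors of log2 fold changes were derived from the F statistic. The common biological coefficient of variation was 14.9%, and 5 residual degrees of freedom remained. That number does not subtract what a constant per gene and batch, estimated before deposit, would have used, so the p-values may be too small. The level of Smarca4 was also compared by an exact permutation test of log2 CPM over the 35 splits of the 7 libraries. The choice of test, the rule for named genes, the 28 gene lists and all settings except the batch fits were fixed before the data were examined. The lists were of hair cells, hair bundles, supporting cells, the prosensory domain, the greater epithelial ridge, the cochlear roof, the Notch, FGF, Wnt, BMP and TGF-beta, Hedgehog and planar cell polarity pathways, the BAF complex, the cell cycle, p53 targets, Hox genes, epithelial junctions, periotic mesenchyme, cartilage, neurons, glia, melanocytes, endothelium, erythroid cells, macrophages, skeletal muscle, dissociation stress and embryo sex. Lists with 5 or more tested members were tested with camera in limma 3.58.1 (preset inter-gene correlation of 0.01), with an estimated correlation and with fry beside it, and adjusted over 27 lists. Genes were named by a rule. They are Smarca4, the 12 protein-coding genes with the largest fold change in each direction among those past the threshold, with a mean of at least 1 CPM and all knockout libraries on the same side of all controls, and of each list the members past the threshold, at most 6 by smallest p, or the 2 with the smallest p where fewer than 2 passed. This gave 104 genes, of which 5 are not reported here. Of these, 21 overlap another tested gene in their annotated span, and without strand the reads of such pairs cannot be told apart.

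The edgeR procedure was tested on simulated counts for the knockout against control comparison over 17341 genes with 200 changed genes. It recovered 37.3%, 68.7% and 86.4% of the genes changed by 1.5-fold, 2-fold and 3-fold, and 6.57% of its calls were unchanged genes. A batch shift of assumed size was then added and removed by constants estimated from the simulated libraries. After this, 5.74% of the calls were unchanged genes and 31.3%, 68.7% and 72.7% were recovered. With a batch term in the fit, 3.54% of the calls were unchanged genes and 25.4%, 67.2% and 71.2% were recovered. How the constants behind the deposited values were estimated is not known, so these rates need not hold for them.

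Alternatives were DESeq2 size factors, library size alone and upper-quartile factors; DESeq2 1.42.0, limma-voom and a test against a fold of 1.5; other low-count filters; leaving out each library; the replicate number as a block; limma with trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, and without that filter; protein-coding genes only; libraries without haemoglobin and mitochondrial genes; and 1 surrogate variable from sva 3.50.0. A batch term and a fit on the larger batch alone were added after seeing the data. Figures and the remaining tests used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.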

Results

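The libraries measured transcripts in total RNA of cochlear epithelium from mouse embryos at embryonic day 16. Brg1, the product of Smarca4, is an ATPase of the BAF (SWI/SNF) chromatin remodelling complex, and the series asks what its loss does to differentiation and patterning of the cochlear sensory epithelium. The knockout group held 4 libraries with totals of 18195300, 18503657, 16098269 and 17123693 counts in replicates 1 to 4. The control group held 3 libraries with 18872132, 18251121 and 18678948 counts. Xist and the Y-linked genes varied among the libraries of each group, and 0 of these 5 genes was called between groups by edgeR or DESeq2, or at an unadjusted p below 0.05 (camera adjusted p = 0.798). Of these, Eif2s3y was at a log2 fold change of 0.27 ± 0.66 (SE) and Ddx3y at 0.26 ± 1.28. Mitochondrially encoded genes took 2.80% ± 0.33 of the counts in knockout (SD, n = 4) and 2.43% ± 0.37 in control (SD, n = 3; exact permutation p = 0.257, two-sided), and haemoglobin genes 0.149% ± 0.053 and 0.179% ± 0.032 (exact permutation p = 0.457).

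Smarca4 (ENSMUSG00000032187, chromosome 9, 21616169 to 21704230, mm10, forward strand) was lower in every knockout library than in every control library. It was at 281, 239, 228 and 250 CPM in knockout replicates 1 to 4 and at 372, 356 and 376 CPM in control replicates 1 to 3. Its level was 249 ± 23.0 CPM in knockout (SD, n = 4) and 368 ± 10.9 CPM in control (SD, n = 3), that is 67.8% of the control mean. The log2 fold change was -0.56 ± 0.09 (SE; 95% interval -0.79 to -0.33; edgeR adjusted p = 0.00338), and the exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 3 libraries allow. A gene-level count can include reads from a transcript that lacks the deleted exons and from cells in which the gene was not deleted.

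**Figure D1:**
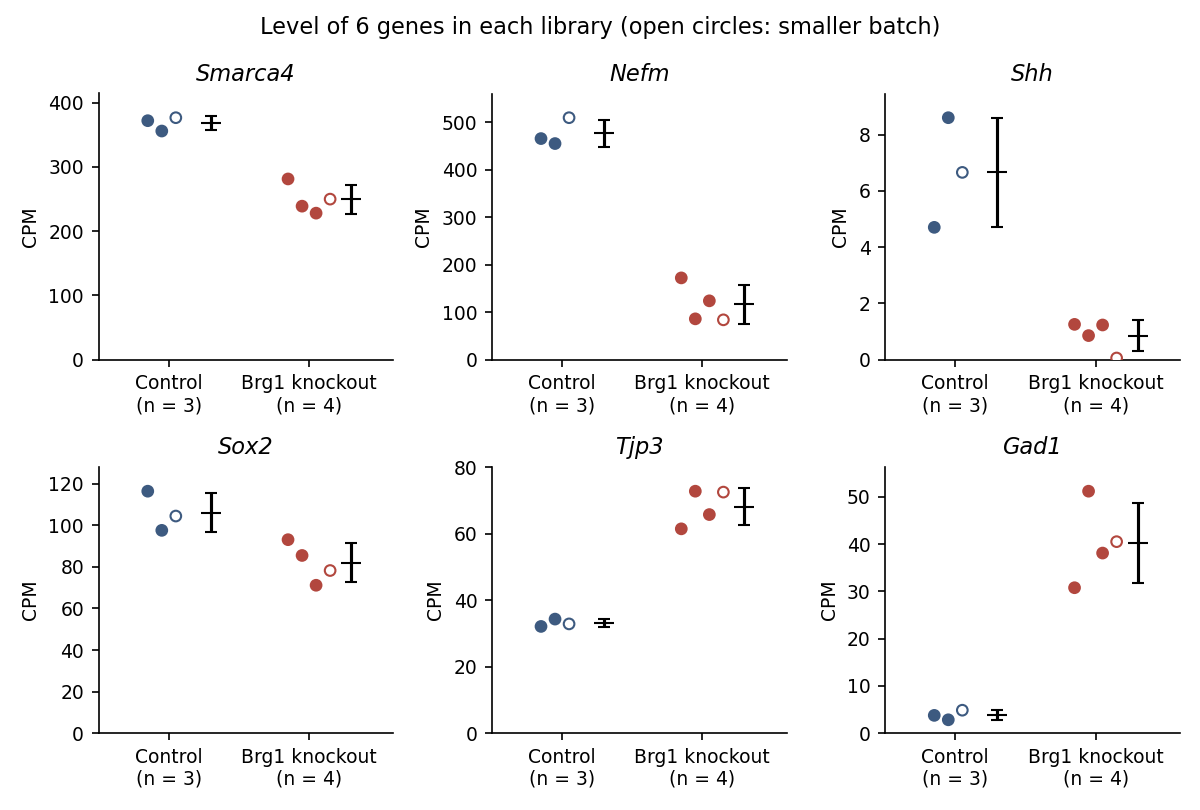
CPM of 6 genes (vertical axes, from 0) in each control and Brg1 knockout library; bars give the mean ± SD of 3 and 4 libraries, and open circles mark the 2 libraries of the smaller batch. Smarca4 averaged 249 CPM in knockout and 368 CPM in control, Nefm 117 and 477, and Gad1 40.1 and 3.82, and the groups do not overlap in any of the 6 genes.

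Against controls, the knockout libraries had 337 genes higher and 845 lower among 17341 tested (edgeR, adjusted p below 0.05; 3673 genes at an unadjusted p below 0.05). The fall was the larger side also by size: 355 genes were lower by at least 2-fold and 72 higher. Among called protein-coding genes at a mean of 1 CPM or more whose groups did not overlap, Gad1, the enzyme that makes GABA (log2 fold change 3.39 ± 0.22 SE; 40.1 ± 8.45 against 3.82 ± 1.01 CPM), and Tmem54 (3.28 ± 0.36) were among those that rose most. Gad1 overlaps the antisense gene Gad1os, which rose by 1.30, and Tmem54 overlaps Hpca on the other strand, which fell by 1.30 on the log2 scale; both were chosen after their values were seen. Cfap44, Dgkk, Ankrd22, Psd4, Icosl, 1700016K19Rik, Cadps2, the signalling ligand Bmp6 and the phosphatase Dusp5 rose by log2 fold changes of 2.09 down to 1.57, and of these Cadps2 reached the highest level (101 ± 16.8 against 32.8 ± 15.7 CPM). In the same set of called genes the largest fall was in Shh, the Sonic hedgehog ligand (-2.95 ± 0.51; 0.851 ± 0.558 against 6.65 ± 1.95 CPM). Next came Chrna3, a nicotinic receptor subunit (-2.89 ± 0.48), the potassium channels Kcnk3 (-2.56 ± 0.43) and Kcnc2 (-2.38 ± 0.27), and Th, the enzyme that starts catecholamine synthesis (-2.38 ± 0.37). Spp1, which encodes osteopontin, fell from 97.2 ± 11.2 to 19.1 ± 7.90 CPM (-2.35 ± 0.32). Dio3, Adarb2, Nrg3, Wnt3 and Uts2b fell by log2 fold changes between -2.28 and -2.16.

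The groups did not overlap in 3597 of the tested genes, or 20.7%, where chance gives 5.71% if the libraries are interchangeable. They did not overlap in 1178 of the 1182 called genes either, which the test itself selects for. Within the larger batch (3 knockout and 2 control libraries) 219 genes were higher and 438 lower; the smaller batch holds 1 library of each group and allows no test. Without control replicate 1 the counts fell to 106 and 450, and without control replicate 2 to 132 and 631.

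The neuron list had the lowest median of the lists tested. Of 21 tested markers of spiral ganglion neurons, the cells that innervate the cochlea, 12 were lower and none higher, with a median log2 fold change of -1.31; adjusted over the list alone, 15 were lower and 1 higher. The neurofilament genes Nefm (117 ± 41.5 against 477 ± 28.9 CPM; -2.03 ± 0.25) and Nefl (-1.90 ± 0.18), whose annotated spans overlap on opposite strands, and the growth cone gene Gap43 (-1.22 ± 0.12) were among them, with Snap25 and Prph. Markers of Schwann and satellite glia moved with them: 3 of 13 were lower, namely Foxd3 (-1.66 ± 0.17), Cdh19 (-1.13 ± 0.27) and the myelin gene Mbp (-0.54 ± 0.14), and 8 were lower adjusted over the list alone. The camera adjusted p was 1.94e-13 for neurons and 5.94e-05 for glia, against adjusted p = 0.182 and adjusted p = 0.403 with an estimated correlation. Within the larger batch the neuron median was -1.17, with 5 members called lower, and 1 glial gene was called lower.

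Several epithelial genes went the other way. Of 30 tested genes of epithelial identity and junctions, 11 were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.27. The tight junction genes Tjp3 (68.1 ± 5.50 against 33.1 ± 1.12 CPM; 1.04 ± 0.09), Cgn (0.87 ± 0.09), Cldn9 (0.57 ± 0.10) and Cldn3 (0.56 ± 0.10) rose, as did the epithelial splicing factor Esrp2 (0.70 ± 0.14) and the transcription factor Grhl2 (0.46 ± 0.09). The member that fell was Cdh2, which encodes N-cadherin (-0.61 ± 0.12), named here after its value was seen. The camera adjusted p was 8.35e-06, against adjusted p = 0.403 with an estimated correlation. Within the larger batch 8 members were higher and 1 lower, with a median of 0.36. Tjp3, Grhl2 and Esrp2 overlap other tested genes.

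Hair cell genes went both ways. Of 37 tested, 2 were higher and 4 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.145). Called or not, 25 members lay above 0 and 12 below, with a median log2 fold change of 0.23. Gfi1, a zinc-finger factor needed in hair cells, rose from 4.43 ± 1.31 to 8.90 ± 1.49 CPM and Ccer2 by 0.48 ± 0.13 on the log2 scale. In contrast, Mreg (-1.14 ± 0.13), Nhlh1 (-1.29 ± 0.18), Insm1 (-1.11 ± 0.22) and Srrm4 (-0.81 ± 0.19) fell; the last 3 are also used by neurons. Atoh1, the factor that starts hair cell fate, and Pou4f3, which maintains it, were chosen after their values were seen and did not pass the test, at 0.13 ± 0.13 (adjusted p = 0.621) and 0.12 ± 0.09 (adjusted p = 0.465). In the hair bundle list, of stereocilia and mechanotransduction genes, 3 of 29 were higher and none lower (4 and 1 adjusted over the list alone), with a median of 0.54. Gpsm2, which sets bundle shape, rose by 0.55 ± 0.10, the actin bundler Espn by 0.77 ± 0.16 and Tmie, a part of the transduction channel, by 0.58 ± 0.14. The camera adjusted p of 0.00204 became adjusted p = 0.542 with an estimated correlation. Within the larger batch it was 0.0524, 1 member was called higher and the median was 0.30.

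**Figure D2:**
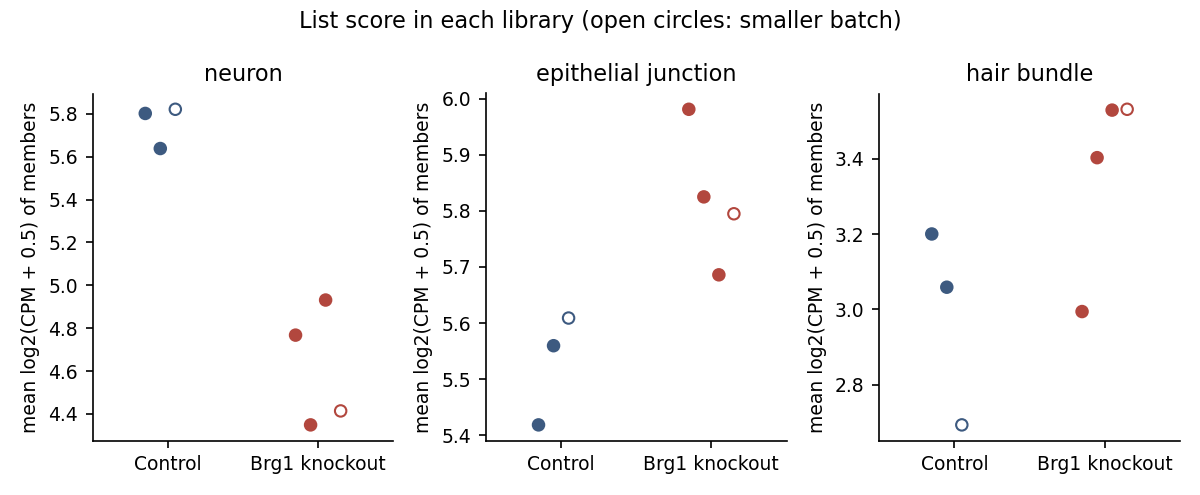
Mean log2(CPM + 0.5) of the members of 3 lists (vertical axes) in each control and Brg1 knockout library; open circles mark the 2 libraries of the smaller batch. Within the larger batch the difference between groups was -1.04 for neurons, 0.34 for epithelial junctions and 0.18 for hair bundles.

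Genes of the prosensory domain, the precursor field of the organ of Corti, were lower where they were called. Of 23 tested, 5 were lower and none higher (7 lower adjusted over the list alone), with a median of -0.13. Among them were the Notch modulator Lfng (-0.73 ± 0.12), Eya1 (-0.41 ± 0.08), Hmga2 (-0.93 ± 0.21) and Sox2 (82.0 ± 9.43 against 106 ± 9.53 CPM; -0.37 ± 0.10). The camera adjusted p of 0.0139 became adjusted p = 0.403 with an estimated correlation and 0.0542 without knockout replicate 3. Among 15 genes of the medial greater epithelial ridge and the tectorial membrane, 1 was higher and 2 lower (1 and 3 adjusted over the list alone; median -0.22). Fgf10 fell from 107 ± 17.5 to 55.0 ± 7.95 CPM (-0.96 ± 0.13) and Epyc from 510 ± 116 to 179 ± 57.4 CPM (-1.51 ± 0.28), while Otogl, a tectorial membrane component, rose by 0.59 ± 0.13. That list's camera adjusted p of 0.0312 became adjusted p = 0.386 with an estimated correlation and 0.0664 and 0.0623 without knockout replicates 1 and 3. Of 24 supporting cell genes, Ngfr (-1.72 ± 0.20) and Igfbpl1 (-1.40 ± 0.21) were the 2 that fell and none rose (5 lower adjusted over the list alone; camera adjusted p = 0.142; median -0.03). Ngfr is also made by glia. Of 18 genes of the cochlear roof and stria vascularis, Cldn9 and Slc12a2 (0.64 ± 0.13) were the 2 that rose and none fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.458).

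**Figure D3:**
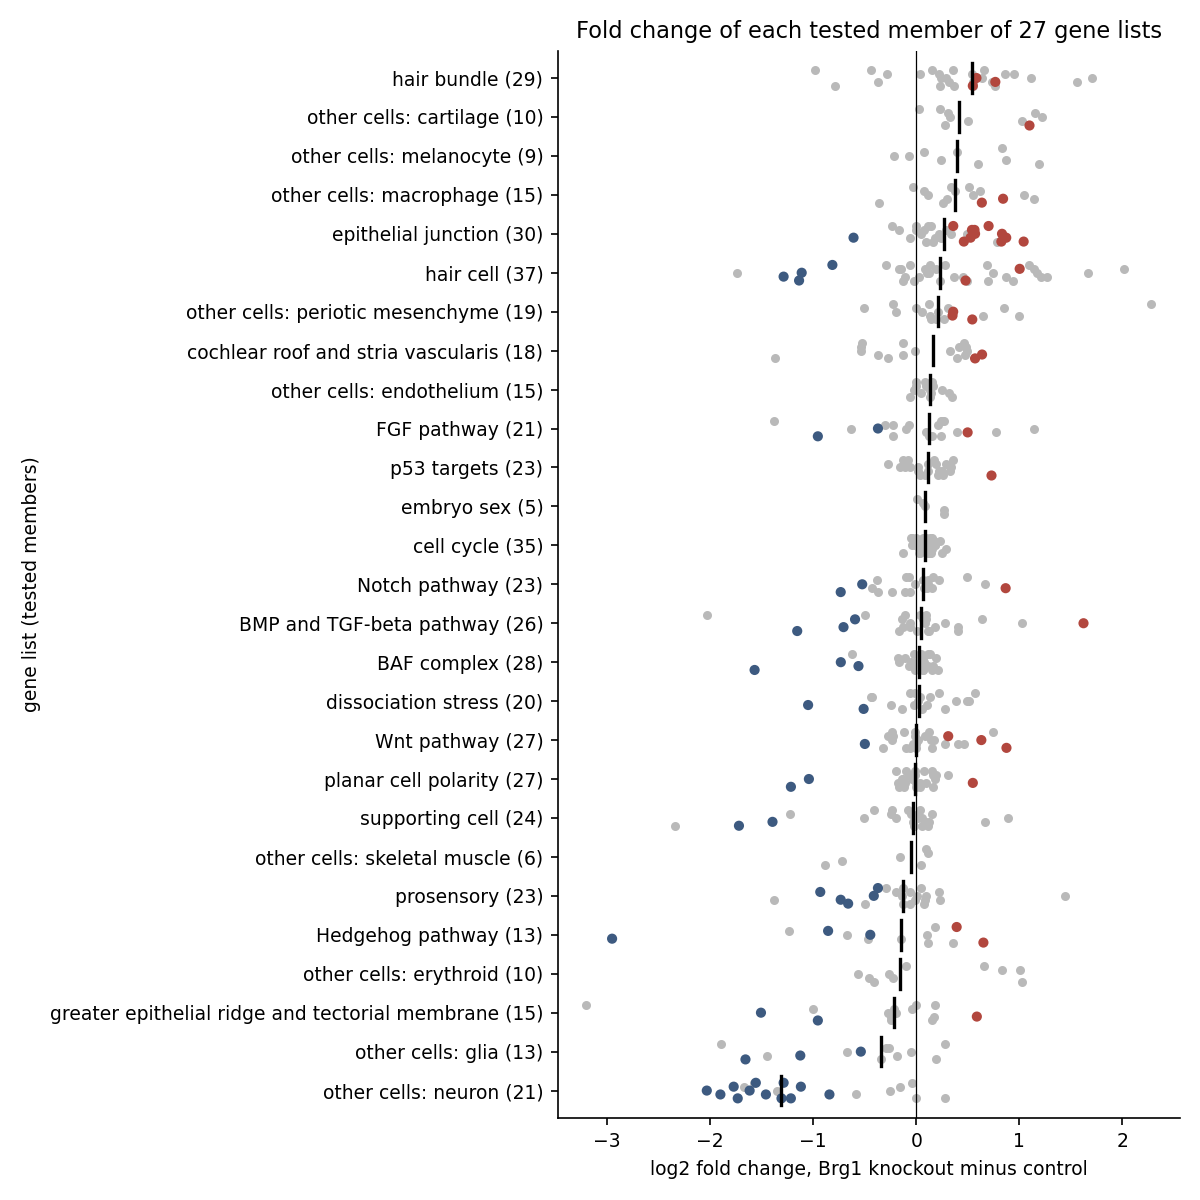
Log2 fold change, Brg1 knockout minus control (horizontal axis), of each tested member of the 27 lists with 5 or more tested members, ordered by median; black bars are list medians, red and blue points are members called higher and lower, grey points are not called. The neuron list has the lowest median (-1.31) and the hair bundle list the highest (0.54).

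Signalling pathway lists held single members that changed, in both directions, and none of these lists passed camera. In the Hedgehog list 2 of 13 were higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.626), with a median of -0.15, or 0.02 in the larger batch alone. The target Ptch1 (-0.45 ± 0.09) fell with Shh, and the coreceptors Cdon (0.65 ± 0.09) and Boc (0.39 ± 0.10) rose. Which cells account for these changes was not tested. Neuron genes were lower in the same libraries (list median -1.31), so the fall of Shh cannot be placed in the epithelium. The mean log2(CPM + 0.5) of the Hedgehog list lay between 4.70 and 4.97 in the knockout libraries and between 5.10 and 5.20 in the controls. Of the 27 lists, 8 had a mean lower in every knockout library than in every control and 5 higher, where chance gives 5.71% if the libraries are interchangeable. Planar cell polarity was among the 8, at 5.78 to 5.88 against 5.89 to 5.94. In the Notch list 1 of 23 was higher and 2 lower (the same numbers adjusted over the list alone; camera adjusted p = 0.933, direction down with a median of 0.06): Nrarp, a feedback target, rose by 0.87 ± 0.19 and Heyl fell by 0.52 on the log2 scale, beside Lfng. In the FGF list 1 of 21 was higher and 2 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.802): Fgf9 rose by 0.50 ± 0.09, and Fgf10 and the target Dusp6 (-0.37 ± 0.10) fell. In the Wnt list 3 of 27 were higher and 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.751); the secreted inhibitors Wif1 (0.87 ± 0.18), Dkk2 (0.63 ± 0.17) and Sfrp2 (0.31 ± 0.08) rose and Wnt7a (-0.50 ± 0.11) fell. In the BMP and TGF-beta list 1 of 26 was higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.881, direction down with a median of 0.05): Bmp6 rose by 1.62 ± 0.31, and Chrdl1 (-1.16 ± 0.16), Tgfb2 (409 ± 63.8 to 251 ± 16.1 CPM) and Id4 (-0.59 ± 0.14) fell. In the planar cell polarity list 1 of 27 was higher and 2 lower (the same numbers adjusted over the list alone; camera adjusted p = 0.798): Celsr3 (-1.22 ± 0.14) and Insc (-1.04 ± 0.27) fell and Gpsm2 rose.

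Of 28 subunits of the BAF complexes, 3 were lower and none higher, also adjusted over the list alone (camera adjusted p = 0.751, direction down with a median of 0.03). Beside Smarca4 these were Actl6b (5.97 ± 1.87 against 17.7 ± 0.374 CPM; -1.57 ± 0.21) and Dpf1 (-0.73 ± 0.16), both known as subunits of the neuronal form of the complex. Of 35 cell cycle genes, 0 were called by edgeR, also adjusted over the list alone, and 0 by DESeq2, while 2 were higher and 0 lower at an unadjusted p below 0.05. The list had a median of 0.09 and a camera adjusted p of 0.0247, against adjusted p = 0.692 with an estimated correlation. It did not pass without knockout replicate 1 or 2 or control replicate 1 or 2 (0.0664, 0.132, 0.0906 and 0.0591). Its smallest p were those of Ccnb2 (0.25 ± 0.08) and Cdc6 (0.29 ± 0.11). Of 23 p53 targets, Plk2 rose by 0.72 ± 0.14 and the others did not pass, also adjusted over the list alone (camera adjusted p = 0.0855); Apaf1 was next at 0.33 ± 0.10. Only 2 of 39 Hox genes were expressed enough to test, Hoxa2 at -0.36 ± 0.24 and Hoxd8 at 0.04 ± 0.33, and neither was called by edgeR, by DESeq2 or at an unadjusted p below 0.05.

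Markers of other tissues that a cochlear dissection can carry were looked at in the same way. Of 19 periotic mesenchyme genes 3 were higher, Twist1 (0.54 ± 0.11), Prrx1 (0.35 ± 0.08) and Pdgfra (0.36 ± 0.08), and none lower (6 and 1 adjusted over the list alone), with a median of 0.21. Of 10 cartilage genes, Matn1 was higher, at 40.6 ± 9.27 CPM in knockout (adjusted p = 0.00325), also adjusted over the list alone, and none lower, with a median of 0.41; Col11a1 was at 0.50 ± 0.21. In control replicate 3 alone Acan and Hapln1, chosen after their values were seen, were listed at 0. In the larger batch alone, 2 cartilage genes were higher and 0 lower, with a median of 0.36 and a camera adjusted p of 0.00125. Of 15 macrophage genes, Mrc1 (0.64 ± 0.14) and Tyrobp (0.84 ± 0.22) were the 2 higher and none was lower (3 higher adjusted over the list alone), with a median of 0.38. The camera adjusted p of these 3 lists were 0.0125, 0.00204 and 0.00260, against adjusted p = 0.512, adjusted p = 0.182 and adjusted p = 0.542 with an estimated correlation; the mesenchyme value was 0.0758 without knockout replicate 3. In the larger batch alone the 3 mesenchyme and the 2 macrophage genes did not pass, with list medians of 0.33 and 0.48. Of 9 melanocyte, 15 endothelial, 10 erythroid and 6 skeletal muscle genes, 0 were called by edgeR, also adjusted over the list alone, and 0 by DESeq2 (camera adjusted p = 0.230, 0.102, 0.798 and 0.613). At an unadjusted p below 0.05, 3 melanocyte, 2 endothelial, 0 erythroid and 1 muscle genes differed. The erythroid list had a median of -0.16 and a mean of 0.15. The members with the smallest p were Tyrp1 (1.19 ± 0.44) and Mlana (0.87 ± 0.33), Erg (0.34 ± 0.13) and Egfl7 (0.32 ± 0.14), Hba-x (1.02 ± 0.47) and Hbb-bt (-0.46 ± 0.23), and Tnni1 (-0.89 ± 0.38) and Acta1 (-0.72 ± 0.76). Of 20 dissociation stress genes, Nr4a1 (-0.51 ± 0.11) and Egr2 (-1.05 ± 0.28) were the 2 lower and none was higher (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.910, direction down with a median of 0.03); Egr2 is also a Schwann cell gene.

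Of the 27 lists, 10 passed camera with the preset correlation and 0 with an estimated correlation. By fry, which asks whether the genes of a list move on balance in 1 direction, the lists of neurons, cartilage, p53 targets and the greater epithelial ridge passed (adjusted p = 0.00672, 0.00618, 0.00672 and 0.0466).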

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

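The tests of the batch adjustment, of the order of counts, of cell shares, of the gene counts over other splits and of splits within batches were chosen after the results were seen; the matched random lists and the splits for gene lists were set out before. In the group of 4 knockout libraries, 6 of 104 measures (the CPM of the genes reported and 5 library measures) had a library far from the other 3, and chance flags about 1 in 20. Knockout replicate 1 stood apart at 1.58 CPM of 1700016K19Rik (others 3.53 to 3.88) and 268 CPM of Otogl (others 179 to 192). Knockout replicate 4 stood apart at 73.4 CPM of Ccer2 (others 54.1 to 56.4), 41.0 CPM of Fgf9 (others 36.2 to 36.9) and 192 CPM of Cldn3 (others 159 to 164). Knockout replicate 3 stood apart at 17.1 CPM of Celsr3 (others 12.2 to 12.8). The control group of 3 was not looked at in this way.

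Of the 35 splits of the 7 libraries into 4 and 3, only the real split gave as many as 337 genes higher or as many as 845 lower. The highest count of the others was 0 in both directions. That share is under 0.05, but these splits treat all libraries as interchangeable, which the batches make uncertain. The splits that keep 1 control-side library in the smaller batch number 20. That is too few for a share under 0.05, so they cannot exclude chance. In these the real values were again 337 and 845, and the highest other 0. Chance was not excluded for the number of gene lists that passed camera with the preset correlation, since 4 of the 35 splits gave as many as the real 10, and the highest of the others was 11, with knockout replicates 1, 2 and 3 on the control side. Of the 20 splits within batches, 2 gave as many lists, and the highest other was 10. Camera's p for the single list was as small in 1 split for neurons, 6 for epithelial junctions and 7 for hair bundles, the real split included. Among the other lists that passed, it was as small in 1 split for cartilage, 2 for glia and 5 for the greater epithelial ridge. The number was 7 for the prosensory list, 8 for macrophages, 9 for mesenchyme and 12 for the cell cycle.

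Of 21 neuron genes, 12 were called lower in knockout, with a camera adjusted p of 1.94e-13, or 0.182 with an estimated correlation. A second list of neuronal genes, of which part had been seen, moved the same way: 46 of 46 tested were below 0 and 40 were called lower, with a median of -1.25. An added constant keeps the order of a gene's counts within a batch, and in the larger batch 15 of 21 members had all 3 knockout counts below both controls, against 21.3% of all tested genes, which argues against the batch adjustment as the whole cause; the list's mean log2 level differed by -1.04 there, a size the adjustment can change. GC content, length and expression level are argued against as well, since 0 of 10000 random lists matched on them had so low a median (lowest -0.18). A lower share of neurons in the tissue taken may be the source. Of the second list, 41.3% lay over 2 SE from a common fall, between the bounds set for and against it. Of the reported list 71.4% did, more than 1 common factor alone would leave. Other cells that express its genes, or the batch adjustment, which changes log fold changes, could also give such a spread, and this was not tested. Fewer neurons and lower expression per neuron therefore cannot be told apart.

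Of 30 epithelial junction genes, 11 were called higher in knockout and 1 lower, with a camera adjusted p of 8.35e-06, or 0.403 with an estimated correlation. Within the larger batch the list's mean log2 level differed by 0.34, and 12 of 30 members had all 3 knockout counts above both controls, against 8.28% of all tested genes, which argues against the batch adjustment as the whole cause. In addition, 0 of 10000 matched random lists had so high a median (highest 0.14), which argues against GC content, length and expression level. A higher share of epithelium in the tissue remains possible: of 37 other epithelial genes 30 were above 0 and 5 called higher (median 0.21), and 35.1% of them and 46.7% of the reported list lay over 2 SE from a common rise. The batch adjustment can also scatter these folds, so their spread cannot decide the question. Mesenchyme, cartilage and macrophage markers also lay higher in every knockout library by their list means (medians 0.21, 0.41 and 0.38), which argues against epithelium having displaced all other tissue alike. In contrast, the supporting cell, prosensory and greater epithelial ridge lists lay lower in every knockout library by their means (medians -0.03, -0.13 and -0.22). A higher share of all epithelium alone would not lower them. The supporting cell and ridge means, however, rest partly on a few members. Among these are Ngfr, also made by glia, and Calb1, listed at 0 in knockout replicate 1. Of the supporting cell genes 11 lay above 0 and 13 below, so their lower mean is weak evidence about the epithelial share. The means of the hair cell, hair bundle and cochlear roof lists overlapped between groups. A share lost by neurons alone stays open, so a changed share and regulation of single genes such as Tjp3 cannot be told apart.

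Of 29 hair bundle genes, 3 were called higher in knockout, and 1 in the larger batch alone; the list means of the groups overlapped, and the list had a camera adjusted p of 0.00564 without knockout replicate 4, 0.0155 without control replicate 3, 0.00554 with the batch term, 0.0524 in the larger batch alone, 0.0890 with 1 surrogate variable and 0.542 with an estimated correlation. The mean log2 level of the list differed by 0.84 between the 2 libraries of the smaller batch and by 0.18 within the larger batch, under 1 SD of the libraries (0.24), with knockout replicate 1 below both controls, although by the order of counts there 6 of 29 members had all 3 knockout libraries above both controls (8.28% of all tested genes) and 3 below (21.3%), and Gpsm2, Espn and Tmie were above in CPM. The batch adjustment is a candidate explanation for part of the fold: 24 genes were listed at 0 in control replicate 3 and at 1 CPM or more in all others (at most 5 such genes in any other library), among them Otof, Loxhd1, Strc, Acbd7 and Cabp2 of the hair cell and bundle lists and the cartilage genes Acan and Hapln1, as subtraction below 0 would leave, and a subtracted constant inflates log folds while it leaves count differences as they were. GC content, length and expression level are argued against (0 of 10000 matched lists, highest 0.24). A difference between the genotypes in hair cells stays open, as untested.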

How the results depend on the processing

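The fits with a batch term and on the larger batch alone were chosen after seeing the data. No gene called in the report changed sign in any setting that tested it. Genes higher, 337 as reported, numbered 517 with DESeq2, 15 against a fold of 1.5, 213, 193 and 63 with log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter, 207 with the batch term, 219 in the larger batch alone and 106 to 348 when a library was left out (106 without control replicate 1, 132 without control replicate 2, 166 without knockout replicate 2, 207 without knockout replicate 3). Genes lower, 845 as reported, numbered 140 against a fold of 1.5, 550 and 302 with log2(FPKM + 0.1) and with log2(FPKM + 1) without a filter, 536 with 1 surrogate variable, 438 in the larger batch alone and 450 to 847 when a library was left out (450 without control replicate 1). The settings not named in this paragraph or with the replicate block stayed within 1.5 times of both counts. Fewer libraries or residual degrees of freedom account by construction for part of these falls; other causes were not tested.

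Whether replicate numbers pair the libraries could not be decided. The deviations of the pairs by title number correlated at -0.10, -0.18 and 0.03. Those of knockout replicate 4 and control replicate 3, which share a number in the descriptions and a batch, correlated at -0.46. Deviations cancel within each group, and a constant removed per batch also removes what the libraries of the smaller batch share, so these values cannot exclude pairing. With the replicate number as a block the counts were 180 higher and 607 lower by title and 74 and 536 by description (12.1% of calls higher, against 28.5% as reported), and endothelium gained a call by description (adjusted p = 0.0458).

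Smarca4 kept its fall, at log2 fold changes from -0.62 to -0.52 and adjusted p from 7.70e-08 to 0.0388, except against a fold of 1.5 (log2 fold change -0.56, no call), which asks for more than its interval excludes. For the other 103 named genes, 2554 values were recomputed: 2089 kept their side of the threshold, 458 lost the call, 59 of these against a fold of 1.5, 7 gained it and 0 reversed; 31 of the 87 called genes passed in every setting but that fold test.

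With an estimated correlation no list passed: adjusted p = 0.542 (hair bundle, macrophage), 0.403 (prosensory, epithelial junction, glia), 0.386 (greater epithelial ridge), 0.692 (cell cycle), 0.512 (mesenchyme) and 0.182 (cartilage, neuron). Hair bundle was 0.0890 with 1 surrogate variable and 0.0524 in the larger batch; supporting cell 0.0346 without a filter; endothelium 0.0324 with 1 surrogate variable and 0.0269 in the larger batch. With a library left out, the adjusted p ranged from 0.0386 to 0.455 (hair cell), 0.0397 to 0.353 (supporting cell), 0.00444 to 0.0542 (prosensory), 0.0146 to 0.0664 (greater epithelial ridge), 0.00215 to 0.132 (cell cycle), 0.00295 to 0.0758 (mesenchyme), 0.0320 to 0.896 (melanocyte) and 0.0347 to 0.408 (endothelium). Calls were lost without knockout replicate 1 (greater epithelial ridge, cell cycle), 2 (cell cycle) or 3 (prosensory, greater epithelial ridge, mesenchyme) and control replicate 1 or 2 (cell cycle). They were gained without knockout replicate 1 (hair cell, endothelium) or 2 (supporting cell, melanocyte) and control replicate 2 (supporting cell) or 3 (endothelium). The cause was not tested.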

Other observations

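The family counts and the single genes here were chosen after the data were seen. Gene families were compared with all 17341 tested genes by Fisher's exact test (two-sided), over 51 families and 102 tests, all of which were adjusted together; genes are not independent replicates. In 5 families the share of lower genes differed from the 4.87% of all tested genes, and in 0 families the share of higher genes did. Of 76 genes of potassium channel subunits and partners (symbols starting with Kcn), 20 were lower and 1 higher (adjusted p = 3.81e-08). Of 19 genes with symbols starting with Cacn, most of them calcium channel subunits, 8 were lower and 1 higher (adjusted p = 7.34e-05), of 20 genes with symbols starting with Tuba, Tubb or Tubg 6 were lower (adjusted p = 0.00962), and of 4 stathmins 3 were lower (adjusted p = 0.0113). Of the lower genes, Tubb3 and Stmn2 are also in the neuron list, and Stmn4 and Cacna1b in the second list of neuronal genes. Genes with Zfp symbols were lower less often than all genes, at 6 of 374 (adjusted p = 0.0286). Homeobox factors, with 5 of 72 higher, and basic helix-loop-helix factors, with 8 of 67 lower, did not pass (adjusted p = 0.147 for both).

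Some genes outside the rule had large changes. Neurod2, a neuronal helix-loop-helix factor, was at 1.04 ± 0.102 CPM in control (SD, n = 3) and listed at 0 in 3 of the 4 knockout libraries. The long noncoding RNA D130009I18Rik fell from 9.46 ± 1.05 to 1.08 ± 0.392 CPM (-3.13 ± 0.26 SE). On the higher side, Pls1 rose from 51.1 ± 9.94 to 109 ± 17.1 CPM (1.09 ± 0.15). Calb1 had a mean of 77.9 CPM in control and 8.56 in knockout, but it was listed at 0 in knockout replicate 1 and was not called by edgeR (-3.20 ± 1.18; adjusted p = 0.209).

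Within 10 megabases on each side of Smarca4 on chromosome 9, 0 of 123 other tested genes were higher and 8 lower, or 6.50%. Of all tested genes, 1.94% were higher and 4.87% lower, or 6.82% called in either direction. The flanking genes had a median log2 fold change of 0.04. Knockout replicate 1 and control replicate 2 held the same value for each of Ddx3y (61.7), Eif2s3y (418), Kdm5d (164) and Uty (7), as a count of 0 moved by 1 constant per gene and batch would leave.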
